A study of Mus musculus with 4 samples.

How the data were processed

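RNA from whole ears of 2 wild-type and 2 mutant mice, taken 48 h after DNFB and labelled from 100 ng per sample, was hybridised to 4 one-colour (Cy3) mouse expression arrays of 1 slide that were read in the same scan. Per the file headers, the deposited spot intensities came from Agilent Feature Extraction 10.7.3.1, which subtracted a spatially fitted background, corrected a multiplicative trend and put surrogate values in place of dim spots, with no scaling between arrays and probe positions on mouse build mm9 (NCBI37). The deposited raw mean signal of a spot and the median of its local background are intensities without any correction, per the file headers. The deposited flags, per the file headers, are values of 0 or 1 for each spot and say whether it was well above background, saturated or an outlier. The authors' series table holds, for each spot, the linear ratio of its processed intensity to the array median, as deposited. This was found from the values, which matched that ratio for 59305 spots per array within 1.5e-05 on the log2 scale, with a median of 1 on each array.

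The 3671 control spots were left out. The processed intensities of the other 59305 spots were put on the log2 scale, and the 75th percentile of each array, between 588.67 and 663.55 in intensity, was subtracted. Spots with an outlier flag (98 and 101 on the arrays of wild-type mice 1 and 2, and 93 and 194 on those of mutant mice 1 and 2) were left out, and spots of the same probe were averaged, which left 55596 of 55681 probes. A probe was tested when its spots were well above background on both arrays of at least 1 group, which 33675 probes were (60.57%). Each gene was represented by its tested probe with the highest mean signal, which gave 23633 genes, of which 9127 carried a clone, accession or predicted name. Gene names are those of the files, replaced by the current symbol for 1564 of the 15318 genes whose accession matched the RefSeq table. No genome sequence or exon annotation was at hand, so that the place of a probe within its gene is not given.

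The comparison was mutant minus wild type, fitted with lmFit and eBayes of limma 3.58.1 (default settings) in R 4.3.3, with the package data.table (version 1.17.8) to read files and matplotlib 3.10.9 in python 3.11.15 for figures. All tests were two-sided. The fit had 2 residual and 2.5 prior degrees of freedom, and the median standard error of a log2 fold change was 0.133. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, at a threshold of 0.05. Exact permutation of 2 against 2 samples cannot reach that threshold, since there are only 2 other splits. Errors given with ± are limma's moderated standard errors, with 2 mice per group. The labels give both groups the replicate numbers 1 and 2 without saying what they mean, so that no pairing entered the model. On simulated data with the variances of these arrays, over 20 runs, 5.99% of the genes called were unchanged ones, a list shifted by 0.5 on the log2 scale was called in 100% of the runs, and 0% of unchanged lists of independent genes were called. Genes in these data are correlated, which the simulation did not include.

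Gene lists of pathways, epidermal programmes, cell types that an ear can hold and technical signals, 40 in all, were written down before the data were examined. Lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, and adjusted over 39 lists. The list of sex-linked genes had fewer and served only to compare the samples. Camera asks whether a list's genes shift relative to all other genes. It was repeated with an estimated correlation and beside fry, which asks whether the genes of a list move one way (directional) or in either direction (mixed), without comparing them with other genes. At the preset correlation camera's degrees of freedom come from the number of genes, not of mice. With an estimated correlation they are the 2 residual ones of the fit. The counts of members adjusted over the list alone use the same p-values, adjusted within the list.

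The genes named are Rela, then for each direction up to 12 genes with the largest change among those past the threshold with no overlap between the groups and a full symbol, filled where fewer passed from the genes with the largest change at an unadjusted p under 0.01 and no overlap, then up to 4 members of each list described with the largest change, those past the threshold first, and sex-linked genes. Genes named outside this rule are given as chosen after their values were seen.

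Alternatives were normexp background correction of the raw signal with an offset of 50, quantile normalization, centring on the array median, the percentile over probes above background on all arrays, the values of the series table, no filter on dim probes, probes above background on all 4 arrays, the mean of all detected probes of a gene, eBayes with trend and robust, array weights, the replicate number as a block, adjusted p under 0.1, a fold of at least 2, and leaving out each mouse in turn. In the last case 1 group held a single sample, which was assumed to vary like the other group. Chosen after the data were seen were leaving out 1 corner of the array (rows up to 120 and columns from 140), a crossed replicate block and leaving out the genes of 2 chromosome segments. No group had the 4 samples that a test for outlying samples needs.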

Results

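Gene expression was measured in whole ears of 4 mice, 48 h after the ears had been painted with 2,4-dinitrofluorobenzene (DNFB), a contact allergen that inflames the skin. In 2 of the mice RelA, the p65 subunit of the transcription factor NF-kB, had been deleted with a Cre recombinase driven by the keratin 14 promoter, which is active in the basal keratinocytes of the epidermis and its appendages. These are called the mutant mice. The other two carried the same floxed RelA allele without the recombinase and are called wild type. Each ear gave 1 one-colour array, and the deposited intensities had an array median of 54.6 and 48.8 in wild-type mice 1 and 2 and of 48.8 and 47.2 in mutant mice 1 and 2. Between 61.21% and 64.27% of the spots on an array were well above background and 0 spots were saturated. Across genes, which are not independent replicates, the arrays of the wild-type mice and mutant mouse 1 correlated with Pearson's r between 0.9925 and 0.9931, and each with that of mutant mouse 2 with r between 0.9827 and 0.9878. On the first principal component (58.8% of the variance) mutant mouse 2 stood at 55.62, wild-type mice 1 and 2 at -16.99 and -31.47 and mutant mouse 1 at -7.155. Its array has a damaged corner. Over the 22499 genes with a probe outside the corner, r with this array lay between 0.9883 and 0.9935, and on the first component (49.8%) mutant mouse 2 stood at 37.23, mutant mouse 1 at 6.861 and the wild-type mice at -10.97 and -33.12. Xist was well above background on 4 arrays and Ddx3y, Uty, Eif2s3y and Kdm5d on 0 arrays. No ear without DNFB was among the 4 samples, so that all values describe inflamed skin and the response to DNFB itself was not measured.

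The comparison of mutant with wild-type ears asked how gene expression in inflamed skin differs with the loss of RelA in the epidermis. Only the mutants carried the recombinase, so that effects of carrying it cannot be told apart from those of the deletion. Rela itself stood at 4.48 and 4.60 in wild-type mice 1 and 2 and at 4.59 and 4.72 in mutant mice 1 and 2, as log2 intensity relative to the array's 75th percentile, and did not pass the test. The spot of Rela lies in the damaged corner of the array of mutant mouse 2, which limits that value. Each at its only tested probe, Snhg12, a host gene of small nucleolar RNAs, and the transcript 2610507I01Rik had lower values in the mutants. Fam183b, a gene of ciliated cells, and Nkx2-9, a homeobox gene, had higher ones, also at their only tested probes. As groups, genes of stressed keratinocytes, antimicrobial peptides, p53 targets, melanocyte genes, immediate early genes and eosinophil markers were among the lists that limma's camera called higher in the mutants, and genes of cytotoxic lymphocytes, B cells, sebaceous glands and adipocytes were among those it called lower. None of the 17 called lists kept its call with an estimated correlation between genes (smallest adjusted p = 0.653 with an estimated correlation). That test has only the 2 residual degrees of freedom of the fit, so a lost call does not show that correlated genes made it. Targets of NF-kB that feed back on the pathway were not called. Of 23633 genes tested with limma, 2 were higher and 2 lower at an adjusted p under 0.05, and 1538 had an unadjusted p under 0.05, of which 699 were higher and 839 lower, where chance would give 1182. The 2 mutant values lay on one side of the 2 wild-type values for 8573 genes (36.28%), where chance gives 33.33%. The p-values measure a difference against the spread between the 2 mice of a group, moderated by a spread pooled over all genes. Where a group's values are surrogates for dim spots, their spread is not one between mice. The small number of arrays limits the precision. Data were also simulated with 200 changed genes among 23633. There the same test called 8.13% of genes with a 2-fold change, 80.4% of those with a 4-fold change and 93.4% of those with an 8-fold change. These shares depend on the number of changed genes, since the adjustment is stricter where fewer genes differ. With the few genes called here they do not carry over: 6330403K07Rik, 16.9-fold higher in the mutants, had an adjusted p of 0.108.

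The probe for Rela (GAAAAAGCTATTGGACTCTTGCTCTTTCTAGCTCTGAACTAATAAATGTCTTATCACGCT) lies at chromosome 19, 5648070 to 5648129 in mouse build mm9. Its log2 fold change, mutant minus wild type, was 0.11 ± 0.12 (SE, n = 2 mice per group), with an adjusted p of 0.887. The labels do not give the deleted exons, and a probe outside the deleted part checks nothing. The ear also holds fibroblasts, immune cells, muscle and cartilage, which do not use the keratin 14 promoter. With the damaged corner of the array left out Rela has no value. The difference therefore neither shows nor excludes the deletion. The other NF-kB subunits had log2 fold changes of 0.18 ± 0.14 for Rel, -0.16 ± 0.11 for Relb, 0.11 ± 0.10 for Nfkb1 and -0.11 ± 0.12 for Nfkb2, with 0 of 4 past the threshold over all genes and 0 when adjusted over the list alone.

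Snhg12 (chromosome 4, 131866864 to 131866922) stood at 0.98 and 1.12 in the wild-type mice and at -7.56 and -7.73 in the mutants, where its spot was not well above background. For such genes a fold is given as a lower bound, with the dimmer group set to the dimmest value that was well above background on each array, or to its own value where that was brighter. It is a bound for the processed intensities only, not under another background correction. At its probe Snhg12 was at least 87.6-fold lower in the mutants (adjusted p = 0.00128). On the reference genome this probe spans fewer bases than its sequence holds, unlike the probes of the other called genes. Whether it matches the sequence of these mice was not tested. Each of the 4 called genes had only 1 tested probe, so that no other probe checks these differences. The transcript 2610507I01Rik (chromosome 11, 59011304 to 59011363) was 21.8-fold lower, with a log2 fold change of -4.45 ± 0.13 and an adjusted p of 0.0148. It carries a clone name and was named after its values were seen. Fam183b (chromosome 11, 58606357 to 58606416) was at least 2.59-fold higher and Nkx2-9 (chromosome 12, 57712410 to 57712469) at least 2.04-fold higher, each with an adjusted p of 0.0413, and neither was well above background in a wild-type mouse. Values of a group near background are surrogates whose spread is not one between mice, which limits these p-values and that of Snhg12. The calls were lost without wild-type mouse 1 and without wild-type mouse 2, though the log2 fold changes hardly moved. In that order they were -8.77 and -8.63 for Snhg12 and -4.44 and -4.45 for 2610507I01Rik. Fam183b had 3.23 and 3.06 and Nkx2-9 3.115 and 3.138. Without mutant mouse 1 the calls were kept. In that case 23 genes were higher and 61 lower in all, but mutant mouse 2 alone stood for its group, and 57 of the 61 had their probe in the damaged corner of its array, 37 of them dark there, and 2 of the 23. Without mutant mouse 2 only Snhg12 kept its call (0.0216; 0.0574 for 2610507I01Rik, 0.103 for Fam183b and 0.0958 for Nkx2-9). With normexp background correction the log2 fold changes were -4.36 for Snhg12 and -2.66 for 2610507I01Rik, both still called, and 0.66 for Fam183b and 0.62 for Nkx2-9, both with an adjusted p of 0.257. For Snhg12, Fam183b and Nkx2-9 these are smaller in size than the bounds above, which are 6.45, 1.37 and 1.03 on the log2 scale. Fam183b and Nkx2-9 also lost their calls with quantile normalization (0.0631 and 0.0849), the percentile over probes above background on all arrays (0.0698 and 0.0602), no filter on dim probes (0.276 each), the replicate block (0.205 each) and the chromosome segments left out (0.0555 each), and Nkx2-9 with eBayes with trend and robust (0.0615). The transcript 2610507I01Rik lost its call with no filter on dim probes (0.122) and with the replicate block (0.137). With the crossed replicate block 1 of the 4 genes, Snhg12, was called. Over the 15 to 17 other alternatives run for each, the adjusted p ranged from 9.9e-06 to 0.169 for Snhg12, from 0.0002 to 0.236 for 2610507I01Rik and from 0.017 to 0.276 for both others.

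**Figure D1:**
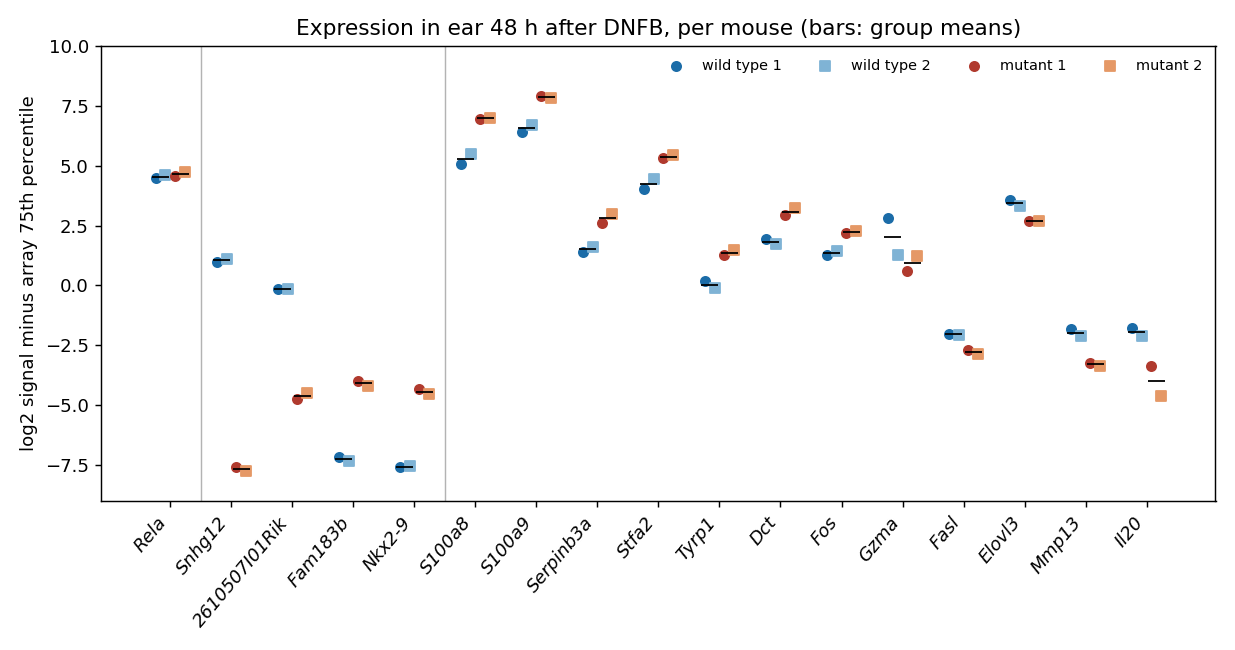
Log2 intensity of Rela, the 4 genes past the threshold and selected named genes on each of the 4 arrays, relative to the 75th percentile of the array, with 1 point per mouse and a bar at the mean of each group. Rela lies between 4.48 and 4.72 in all 4 mice, and Snhg12 lies near 1 in the wild-type mice and below -7.5 in the mutants.

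Snhg12 lay in 1 of 2 short chromosome segments that held 12 of the 60 genes with an unadjusted p under 0.001 and a known position. On chromosome 4, from 128688980 to 133376363, 121 genes were tested, 5 had such a p, and 5 of 5 were lower in the mutants, among them Tmem222 (-1.01 ± 0.12) and S100pbp (-0.85 ± 0.11 at its brightest probe). At the other 2 probes of S100pbp the difference in that direction was 0.195 and -0.0705, against 0.849 at the brightest. On chromosome 11, from 68997387 to 70845694, 119 genes were tested and 7 had such a p, with 4 higher and 3 lower. The edges of a segment are the positions of its first and last gene with such a p, so that these shares follow in part from the choice of the segment. They included Gucy2e, a retinal guanylate cyclase that was not well above background in a wild-type mouse and was at least 1.66-fold higher, Asgr1, a lectin of hepatocytes (1.45 ± 0.16), Alox8 and the transcript 6330403K07Rik (4.08 ± 0.24). Slc16a13 had -0.92 ± 0.10 at its brightest probe, and at its other probe a difference of only 0.204 in that direction. Fam183b and 2610507I01Rik, both past the threshold, lay near each other outside the segment, at 58606357 and 59011304 on the same chromosome. Where the segment ends follows from the rule for its edges, so their place outside it does not separate them from the clustering. The other two splits of the 4 mice, which do not follow genotype, had 0 genes and 1 gene past the threshold over all genes, against 4 by genotype. They had 5 and 5 genes with an unadjusted p under 0.001 and at most 1 and 2 of them in a window of 10 Mb, although up to 7 and 6 of their 60 top genes lay in a window, on chromosomes 12 and 1. The genes of the 2 segments were singled out after their values were seen, and of them only Snhg12 passed the threshold over all genes.

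**Figure D2:**
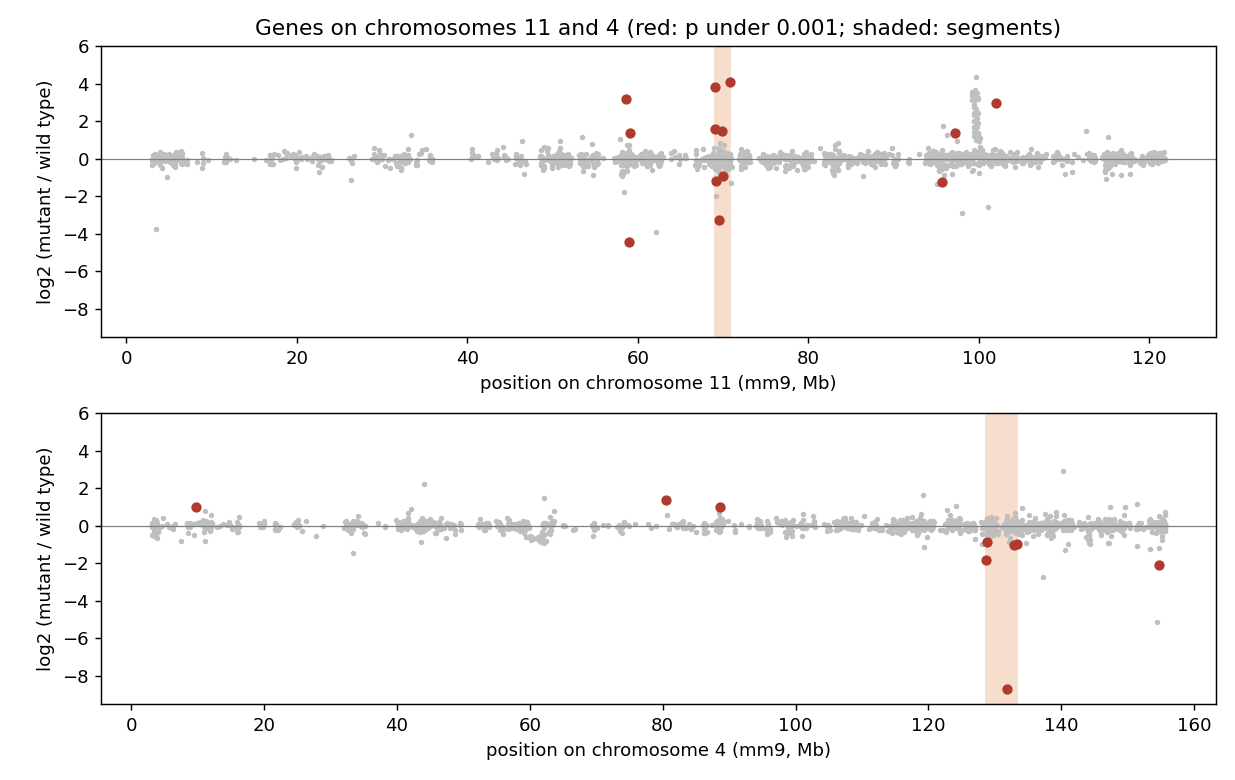
Log2 fold change, mutant over wild type, of every tested gene on chromosomes 11 and 4 against its position in build mm9, with genes with an unadjusted p under 0.001 in red and the 2 segments shaded. The shaded parts hold 7 red points on chromosome 11 and 5 on chromosome 4.

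The genes with the largest differences among those with an unadjusted p under 0.01 and no overlap between the groups did not pass the threshold, and their values are given as such. Among those with higher values in the mutants, Chil4, a chitinase-like protein of type 2 inflammation, had a log2 fold change of 3.82 ± 0.71 (adjusted p = 0.491). Pyy, which encodes the hormone peptide YY, had 2.98 ± 0.39 (0.386) and Gapdhs, the glyceraldehyde-3-phosphate dehydrogenase of sperm, 2.50 ± 0.21 (0.298), with 2.45 at its other probe. S100a8, a subunit of calprotectin, stood at 5.05 and 5.49 in the wild-type mice and at 6.97 and 6.98 in the mutants. The urate oxidase gene Uox (2.20 ± 0.50) and the melanocortin receptor gene Mc1r (2.05 ± 0.40) had higher values too. Alox8 was at least 3.37-fold higher, Robo3 at least 2.58-fold and Defb40 at least 1.98-fold. Mid1 was at least 12.9-fold higher at its brightest probe, but its other probes gave -0.20 and 4.36. Among those with lower values, Il20, a cytokine that acts on keratinocytes, had a log2 fold change of -2.04 ± 0.44 (0.543), Mmp13, a collagenase, -1.32 ± 0.15 (0.386), Ubd, a ubiquitin-like gene induced by interferon, -1.43 ± 0.21 (0.393), and Grp, gastrin-releasing peptide, -2.16 ± 0.42 (0.507). Serpina3j, Vsig2, Klk1b27 and Tac4 lay between -1.87 and -1.36, and Gabra4, Sult2a6 and Sox12 were lower by at least 1.42-fold, 1.87-fold and 2.10-fold. Of genes at least 2-fold apart with no overlap between the groups, 170 were higher and 111 lower in the mutants. Some of the 111 owe this to a dark spot in the damaged corner of the array of mutant mouse 2. Golgb1, for example, stood at 1.93 and 2.02 in the wild-type mice, at 1.91 in mutant mouse 1 and at -7.47 in mutant mouse 2.

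Of 40 gene lists fixed in advance, 39 held at least 3 tested genes, and limma's camera called 9 higher and 8 lower in the mutants at a preset correlation of 0.01 between genes. With a correlation estimated from the 4 arrays camera called 0 lists, and 2 had an unadjusted p under 0.05, the p53 targets and the antimicrobial peptides. Limma's fry, which tests for movement in 1 direction, also called 0 (smallest adjusted p = 0.187), and 6 had an unadjusted p under 0.05. The adjusted p of the 17 called lists with an estimated correlation lay between 0.653 and 0.835. Correlation alone does not explain this, since the degrees of freedom are also fewer. The B and plasma cell list had an estimated correlation of -0.0438, below the preset one. Its unadjusted camera p still went from 2.98e-04 to 0.0657. Only 1 other called list, the antimicrobial peptides (-0.0366), was below the preset correlation, and the p53 targets had 0.0198. All other called lists had higher estimates, from 0.193 for adipocyte genes to 0.899 for red blood cell genes. The preset correlation was therefore low for most of the calls. The p-values at the preset correlation rest on the number of genes, not of mice. Of the 17 called lists 11 kept their call in 13 other settings of the processing, with the crossed replicate block and whichever mouse was left out, and 2 of the other 6 lost it with the crossed replicate block. In the same 11 both mutant medians lay on one side of both wild-type medians, which the call itself favours. Over all genes limma called 0 members of the called lists. Of their 265 tested members, counted once per list, 62 had an unadjusted p under 0.05, against 1538 of all 23633 genes. The call of a list itself favours such members. A list's values below are the median log2 fold change over its tested members and the camera adjusted p.

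**Figure D3:**
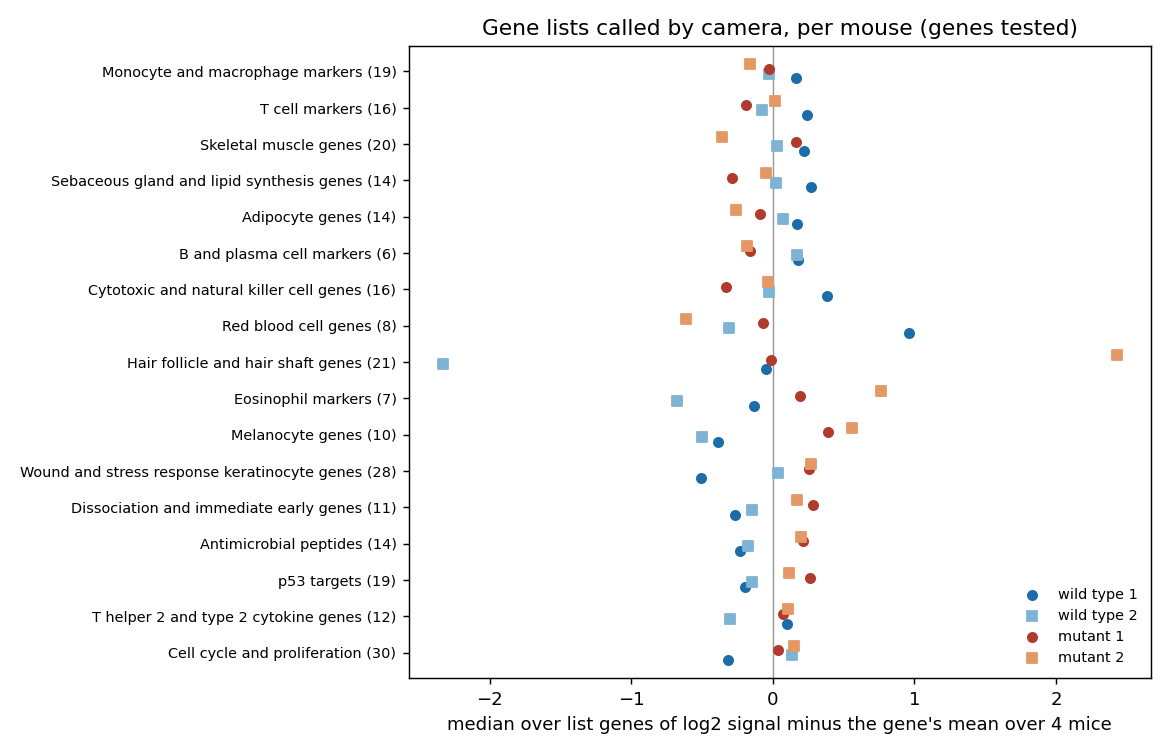
Median, over the tested members of each of the 17 gene lists called by camera, of the log2 signal minus the gene's mean over the 4 mice, with 1 point per mouse. The number of genes tested stands beside each list's name. The melanocyte medians are 0.39 and 0.56 in the mutants and -0.39 and -0.50 in the wild-type mice, and the hair follicle medians range from -2.33 in wild-type mouse 2 to 2.43 in mutant mouse 2.

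Keratinocyte genes of the wound and stress response rose, with a median log2 fold change of 0.51 (adjusted p = 1.1e-11; adjusted p = 0.739 with an estimated correlation). Of 28 tested members 26 had higher values in the mutants, 0 passed the threshold over all genes and 4 passed when adjusted over the list alone. Serpinb3a, a protease inhibitor of stressed squamous epithelium, had 1.29 ± 0.18, Stfa2, a stefin, 1.14 ± 0.18, Sprr2b, a cornified envelope precursor, 1.23 ± 0.29 and Areg, which encodes the growth factor amphiregulin, 1.21 ± 0.33. Without wild-type mouse 1, whose list median of -0.51 was the lowest of the 4, the difference was 0.22. Antimicrobial peptides rose as well, by a median of 0.39 (1.54e-05; adjusted p = 0.653 with an estimated correlation), with 12 of 14 members higher, 0 past the threshold and 3 past it when adjusted over the list alone. S100a8 (1.71 ± 0.18) and S100a9 (1.30 ± 0.14), the subunits of calprotectin, Defb4 (1.46 ± 0.69), a beta-defensin, and S100a7a (1.07 ± 0.36) had the largest differences. Neutrophils also express S100a8 and S100a9, and the neutrophil list is given further on. Genes of terminal differentiation had a median of 0.03 over 37 members, 23 above 0 and 14 below, and were not called (0.963). The median and the mean were positive while the test leaned lower, and the list was called in opposite directions without mutant mouse 1 (0.17, adjusted p = 0.0213) and without mutant mouse 2 (-0.08, 0.0312). The cornified envelope genes Rptn and Flg had 1.16 ± 0.48 and 0.50 ± 0.29, Flg2 had -0.75 ± 0.22 and Lce1m -0.57 ± 0.19. Basal keratinocyte genes had a median of 0.18 (0.0968), with Krt15 at -0.74 ± 0.17 and Cdh3 at 0.60 ± 0.12, and were called without wild-type mouse 2 (0.30, 0.00656).

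The targets of p53, which respond to DNA damage and cell stress, rose by a median of 0.29 (9.29e-09; adjusted p = 0.653 with an estimated correlation). Of 19 tested targets 19 had higher values in the mutants, 0 passed the threshold over all genes and 3 passed when adjusted over the list alone. The largest differences were those of Trp53inp1 (0.80 ± 0.17), Plk2 (0.68 ± 0.23), the death receptor gene Tnfrsf10b (0.65 ± 0.13) and Zmat3 (0.52 ± 0.10). The lists of apoptosis genes themselves were not called. Genes of death receptors and the extrinsic pathway had a median of -0.0036 (0.842), with 2 of 17 past the threshold when adjusted over the list alone, Fasl (-0.74 ± 0.12), which encodes the ligand of Fas, and Tnfrsf10b. Fry called this list when changes in either direction counted (adjusted p = 0.027). Genes of the BCL-2 family and the intrinsic pathway had a median of 0.04 (0.728) with Bax at 0.30 ± 0.11 and Bid at -0.26 ± 0.15. The NF-kB feedback and survival targets had 11 members above 0 and 11 below, a median of 0.0073 and a mean of -0.0043 (0.934), while the test leaned lower. Their largest differences were Bcl2a1d with -0.40 ± 0.16, Nfkbiz with 0.28 ± 0.11, Traf1 with -0.23 ± 0.17 and Tnip1 with 0.21 ± 0.11. The list of NF-kB subunits other than RelA had a median of 0.0022 (0.963) and the test leaned lower. Antioxidant targets of NRF2 had a median of 0.04 (0.892). Genes of the cell cycle had a median of 0.19 and rose (0.00828; adjusted p = 0.835 with an estimated correlation), with 27 of 30 members above 0 and 0 past the threshold by either adjustment. Mcm2 had 0.34 ± 0.13 and Ccne1 0.32 ± 0.15, while Cenpf had -0.54 ± 0.12. The cell cycle call was lost without wild-type mouse 1 (-0.03, 0.549) and without mutant mouse 2 (0.12, 0.30), and the median was 0.43 without wild-type mouse 2. Immediate early genes, which handling of tissue also induces, rose by 0.44 (1.38e-06; adjusted p = 0.677 with an estimated correlation) with 11 of 11 members above 0, 0 past the threshold and 5 past it when adjusted over the list alone. Fosb had 1.10 ± 0.26, Fos 0.89 ± 0.12, Egr1 0.67 ± 0.17 and Nr4a1 0.62 ± 0.32.

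Apart from the type 2 cytokine genes, given with the immune cells below, lists of cytokines and chemokines were not called. Pro-inflammatory cytokines had a median of -0.15 over 16 members (0.0975), with Il20 at -2.04 ± 0.44, its relative Il19 at 1.37 ± 0.34, Il12b at 0.61 ± 0.60 and Osm at -0.50 ± 0.27. They were called lower without mutant mouse 1 (-0.13, 0.00638). The IL-1 and IL-36 family had a median of 0.17 (0.19), with Il1f9 at -0.71 ± 0.27 and Il1f5 at 0.64 ± 0.31. Chemokines that attract neutrophils differed between the 2 mutants. Cxcl1 stood at 0.23 and 0.48 in the wild-type mice, at 2.00 in mutant mouse 1 and at 0.10 in mutant mouse 2. The list median of 0.22 (0.728) became 1.22 without mutant mouse 2 (1.79e-07) and -0.76 without mutant mouse 1 (0.000294). CC chemokines had a median of -0.17 (0.20), with Ccl27a, a chemokine of keratinocytes, at 0.67 ± 0.26, Ccl3 at -0.60 ± 0.19 and Ccl4 at -0.58 ± 0.25, and were called lower without mutant mouse 1 (-0.16, 0.029). Interferon response genes had a median of -0.15 over 38 members (0.231), while Mx2, an antiviral gene, had 1.0 ± 0.12 and was the 1 member past the threshold when adjusted over the list alone. Rsad2 (0.99 ± 0.23) and Ifit1 (0.88 ± 0.21), which type I interferon induces, had higher values, and Gbp2 (-0.87 ± 0.25), which interferon gamma induces, lower ones. Fry called the list when changes in either direction counted (adjusted p = 0.0291), and camera called it lower without mutant mouse 2 (-0.33, 1.9e-06) and with normexp background correction (-0.13, 0.0325). The 3 CXC chemokines that interferon induces had a median of -0.20 (0.272) with Cxcl9 at -0.70 ± 0.29, and were called lower without mutant mouse 2 (-0.55, 0.0171).

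Markers of immune cells moved in different directions. Genes of cytotoxic and natural killer cells fell by a median of 0.42 on the log2 scale (4.47e-07; adjusted p = 0.762 with an estimated correlation). All 16 members had lower values in the mutants, 0 passed the threshold over all genes and 2 passed when adjusted over the list alone. Gzma, a granzyme, had -1.10 ± 0.56, Klrk1, the receptor NKG2D, -0.95 ± 0.30, Fasl -0.74 ± 0.12 and Ncr1 -0.69 ± 0.48. The median was -0.19 without wild-type mouse 1 and -0.19 without mutant mouse 1, and the list was still called, and it was -0.64 without wild-type mouse 2. The list of B and plasma cells fell by 0.37 with 6 of 6 members lower (9.69e-04; adjusted p = 0.653 with an estimated correlation) and 0 past the threshold by either adjustment, Jchain at -0.77 ± 0.19 and Cd79a at -0.40 ± 0.12, and its median was -0.12 with normexp background correction. T cell markers fell by 0.17 (0.00625; adjusted p = 0.828 with an estimated correlation), with 14 of 16 members lower, 0 past the threshold by either adjustment and Cd8a at -0.53 ± 0.29. This call was lost without wild-type mouse 1 (-0.02, 0.812) and without mutant mouse 1 (-0.09, 0.396), and the median was -0.33 without wild-type mouse 2. Eosinophil markers rose by 0.96 (1.42e-05; adjusted p = 0.677 with an estimated correlation), with 7 of 7 members higher, 0 past the threshold and 4 past it when adjusted over the list alone. Prg2, the major basic protein, was well above background on 1 of the 2 wild-type arrays and had 2.12 ± 0.73, and the ribonuclease genes Ear2 and Ear1 had 1.26 ± 0.39 and 1.17 ± 0.36 and Siglecf 0.96 ± 0.25. The list medians were -0.129 and -0.679 in wild-type mice 1 and 2 and 0.196 and 0.765 in mutant mice 1 and 2, the highest in mutant mouse 2. With the damaged corner of its array left out the difference was still 0.96. The eosinophil median was 0.53 with normexp background correction. Type 2 cytokine genes rose by 0.21 (0.0417; adjusted p = 0.828 with an estimated correlation) with 10 of 12 members higher, 0 past the threshold by either adjustment and Il13 at 1.15 ± 0.27. This call was lost without wild-type mouse 2 (0.02, 0.996), without mutant mouse 2 (0.19, 0.314), with no filter on dim probes (0.0583) and with the mean of probes (0.0723), and the median was 0.40 without wild-type mouse 1.

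Neutrophil markers were not called (median -0.09, mean -0.05, adjusted p = 0.879, while the test leaned higher), but 6 of 21 passed when adjusted over the list alone. S100a8, S100a9 and Stfa2l1 (1.01 ± 0.13) had higher values. Fpr1 had -2.41 ± 1.88, from a dark spot in a damaged corner of the array of mutant mouse 2. With the corner left out the list was still not called (-0.08, 0.488). Without that mouse it was called higher (0.22, 0.0214). Monocyte and macrophage markers fell by 0.13 (0.0365; adjusted p = 0.828 with an estimated correlation), with 11 of 19 members lower and 0 past the threshold by either adjustment, Msr1 at -0.70 ± 0.30, Fcgr1 at -0.60 ± 0.22, Lyz2 at -0.56 ± 0.12 and Marco at 0.66 ± 0.29. This call was lost without wild-type mouse 1 (median 0.03) and without mutant mouse 2 (-0.16), and the median was -0.24 without wild-type mouse 2. It was also lost without the genes of the segments on chromosomes 4 and 11 (0.0936), where the median stayed at -0.12. Dendritic and Langerhans cell markers had a median of -0.11 (0.175), and were called lower without wild-type mouse 2 (-0.17, 0.00708) and with normexp background correction (-0.12, 0.0376). Mast cell and basophil markers had a median of -0.12 (0.316), and the basophil protease gene Mcpt8 (-1.06 ± 0.19) was the 1 member past the threshold when adjusted over the list alone. They were called lower without wild-type mouse 2 (-0.19, 0.00708). Markers of gamma delta and dendritic epidermal T cells had a median of 0.09 over 4 tested genes (0.889), and were called higher without wild-type mouse 1 (0.33, 0.0327).

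Melanocyte genes rose by a median of 0.86 (3.12e-11; adjusted p = 0.653 with an estimated correlation), with 10 of 10 members higher in the mutants, 0 past the threshold over all genes and 7 past it when adjusted over the list alone. The pigment genes Tyrp1 (1.35 ± 0.16), Dct (1.26 ± 0.16), Pmel (1.22 ± 0.15) and Oca2 (1.04 ± 0.13) had the largest differences, and the list medians were -0.39 and -0.50 in the wild-type mice against 0.39 and 0.56 in the mutants. With normexp background correction the median was 0.41. Hair follicle and hair shaft genes rose by 2.61 (3.69e-07; adjusted p = 0.828 with an estimated correlation), with 20 of 21 members higher and 0 past the threshold by either adjustment. Their medians were -0.05 and -2.33 in wild-type mice 1 and 2 and -0.01 and 2.43 in mutant mice 1 and 2, so that the mice of a genotype differed by 2.28 and 2.44 and mutant mouse 2 had the highest. With the damaged corner of its array left out the difference by genotype was 2.52. Krt71, an inner root sheath keratin, stood at 2.79 and -0.07 in the wild-type mice and at 3.33 and 6.30 in the mutants, and Krt27 and Krt28 had 3.57 ± 1.41 and 3.46 ± 1.12. The hair median ranged from 1.04 without wild-type mouse 2 and 1.28 without mutant mouse 2 to 3.84 without wild-type mouse 1, and was 1.69 with normexp background correction. Sebaceous gland genes fell by 0.29 (1.21e-05; adjusted p = 0.762 with an estimated correlation), with 13 of 14 members lower, 0 past the threshold and 2 past it when adjusted over the list alone. Elovl3, a fatty acid elongase, had -0.74 ± 0.13, and Awat1 and Far2, enzymes of wax synthesis, had -0.70 ± 0.11 and -0.55 ± 0.19. The sebaceous median was -0.16 without wild-type mouse 1.

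Adipocyte genes fell by 0.29 (2.97e-06; adjusted p = 0.677 with an estimated correlation), with 14 of 14 members lower and 0 past the threshold by either adjustment, Car3 at -0.55 ± 0.19, Lpl at -0.45 ± 0.11 and Pparg, the regulator of fat cell formation, at -0.42 ± 0.11. Skeletal muscle genes fell by 0.21 (3.25e-04; adjusted p = 0.828 with an estimated correlation), with 20 of 20 members lower and 0 past the threshold by either adjustment, Myh7 at -0.81 ± 0.47 and Actn3 at -0.53 ± 0.27. The list medians were 0.222 and 0.0285 in wild-type mice 1 and 2, 0.162 in mutant mouse 1 and -0.36 in mutant mouse 2. With the damaged corner of the array of mutant mouse 2 left out the difference was still -0.21. This call was lost without wild-type mouse 1 (-0.13, 0.0963) and without mutant mouse 2 (0.04, 0.82), and the median was -0.34 without wild-type mouse 2 and -0.50 without mutant mouse 1. Red blood cell genes fell by 0.64 (0.0305; adjusted p = 0.828 with an estimated correlation), with 7 of 8 members lower and 0 past the threshold by either adjustment, Alas2 at -0.84 ± 0.48 and Hbb-bt at -0.82 ± 0.48. This call was lost without wild-type mouse 1 (-0.0038, 0.889), without mutant mouse 2 (-0.34, 0.307) and with no filter on dim probes (0.0601), and the median was -1.28 without wild-type mouse 2. Cartilage genes, with a median of 0.06 (0.188), were called only without wild-type mouse 1 (0.15, 0.0225). Fibroblast (0.05), endothelial (0.05) and Schwann cell genes (0.06) were not called under any setting or with any mouse left out. The Schwann cell mean was -0.03 while its test leaned higher, with Ngfr at -0.63 ± 0.15. Housekeeping genes had a median of 0.04 (0.737).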

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

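Leaving out the array corner, the crossed pairing and leaving out the chromosome segments were chosen after the data were seen; all other alternatives were fixed before the data were examined. The count of genes past the threshold, 2 higher and 2 lower, was the same with array weights, with the array corner left out, at an adjusted p under 0.1 and with a fold of at least 2. Normexp background correction also gave 2 and 2, of which 2 were shared, centring on the array median and the values of the series table gave 3 and 2, and the mean of probes gave 2 and 3. The count was 0 higher and 2 lower with quantile normalization and with the percentile over probes above background on all arrays, and 0 higher and 1 lower with no filter on dim probes (34744 genes tested), with probes above background on all 4 arrays, with the replicate block, with the crossed replicate block (where 9 lists were higher and 6 lower, and 15 of the 17 called lists and 1 of the 4 called genes kept their call) and with the chromosome segments left out. It was 8 higher and 6 lower with eBayes with trend and robust, of which 3 were shared. The counts with 1 mouse left out ranged from 0 to 23 higher and from 0 to 61 lower, with the largest counts without mutant mouse 1, where 57 of the 61 lower genes and 2 of the 23 higher ones had their probe in the damaged array corner of mutant mouse 2. Apart from the crossed replicate block, Snhg12 was called in 13 of 15 alternatives, with an adjusted p between 9.9e-06 and 0.169. The other called genes were called in 12 of 17 (2610507I01Rik), 7 of 16 (Fam183b) and 6 of 16 (Nkx2-9). Rela was called in 0 of 16, with log2 fold changes between 0.03 and 0.18, and has no value with the corner left out because its probe lies there. Mid1 had -0.20 with probes above background on all 4 arrays, since that filter took another of its probes, and the same value at that probe. Of the list shifts 660 kept the sign of the median and their side of the threshold, 62 were no longer called, 14 were newly called and 44 reversed, 41 of them by the sign of the median and the others by the direction of the test. With an estimated correlation 0 lists were higher and 0 lower, and so it was with directional fry. With 1 mouse left out, 9 to 10 lists were higher and 4 to 10 lower, and the median of 18 lists changed its sign. These include 3 called lists, which ranged from -0.031 to 0.43 (cell cycle), -0.24 to 0.027 (monocytes and macrophages) and -0.50 to 0.044 (skeletal muscle). The 15 others were not called: neutrophil-attracting chemokines from -0.76 to 1.22, interferon-inducible CXC chemokines from -0.55 to 0.051, interferon response from -0.33 to 0.077, terminal differentiation from -0.078 to 0.17, neutrophil markers from -0.10 to 0.22, mast cells and basophils from -0.19 to 0.082, gamma delta T cells from -0.099 to 0.33, NRF2 targets from -0.021 to 0.16, endothelium from -0.039 to 0.11, extrinsic apoptosis from -0.053 to 0.031, intrinsic apoptosis from -0.00060 to 0.096, fibroblasts from -0.0060 to 0.073, NF-kB feedback from -0.026 to 0.0040, NF-kB subunits from -0.028 to 0.056 and housekeeping genes from -0.037 to 0.057. The test, but not the median, turned for red blood cells (-1.28 to -0.0038) and type 2 cytokine genes (0.016 to 0.40), and for terminal differentiation without mutant mouse 1. In other settings the median changed its sign for 4 lists near 0 that were not called: NF-kB feedback with normexp (-0.0061), quantile normalization (-0.0065), the percentile over detected probes (-0.0064) and the mean of probes (-0.0078), NF-kB subunits in the same 4 settings (-0.095, -0.011, -0.011 and -0.049), extrinsic apoptosis with normexp (0.027), median centring (0.011), the series table (0.011) and the mean of probes (0.0089), and terminal differentiation with quantile normalization (-0.021). For these ranges, and for the counts, fewer samples or genes entered the test where some were left out, and apart from the corner the cause was not tested. No scaling moved the median of all genes beyond 0.03. Signal over background limits the folds of Snhg12, Fam183b, Nkx2-9 and other genes dim in 1 group, whose values there are surrogates. Their folds are bounds for the processed intensities only, and their p-values rest in part on the spread of surrogates.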

Other observations

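The tests of a base difference under single probes and of strain-derived segments were set before their results were seen, and all other tests here were chosen after the result was seen.

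Genes with small p lay close together on chromosomes 11 and 4: a window of 10 Mb held up to 7 of the 60 genes with a p under 0.001, which a share of 6e-04 of 10000 random placements reached, where 1e-04 is the smallest share they can give, and over genes with a full symbol up to 4 of 35 (0.048), which argues against chance placement, although transcripts with other names may belong to a neighbouring gene. Neighbours that vary together in any split of the mice cannot be told apart from a difference by genotype: the other two splits of the 4 mice had only 5 and 5 genes with such a p (largest windows 1 and 2), while windows of their 60 top genes held up to 7, on chromosome 12 with only probe, accession or predicted names, and 6, on chromosome 1 with Aim2 and Ifi202b, and those of 35 top genes with a full symbol up to 3 and 5, against 4 by genotype. Of the other 228 tested genes of the segments 48.7% had no overlap between the groups, against 36.3% of all genes. Segments of another strain would give such a share. In the windows of the other splits the shares were 34.7% against 30.2% (chromosome 12) and 52.9% against 33.5% (chromosome 1), so that such a share is not particular to genotype. Strain segments that differ along those splits could give these shares too, so the other splits cannot decide. A base difference under single probes stays open too, since the 4 other probes of 3 segment genes had a median difference of 0.2 in the direction of the gene's own probe, with an SD of 1.19, from 2.49 for Gucy2e to 0.204 for Slc16a13 and 0.195 and -0.0705 for S100pbp. Regulation of these regions through the loss of RelA was not tested and stays open, as does a strain difference behind Snhg12.

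The array of mutant mouse 2 held 88 spots at least 4 log2 units below arrays that lay within 1 unit of each other, where the other arrays held 1, 3 and 0, and their median was -6.59. Of these spots 100% lay in 1 corner that holds 4.79% of all spots, while only 11 carried an outlier flag. A local defect would give this pattern. The limits of the corner were chosen after the data were seen, so that the share in it follows in part from that choice. Against genes that were silent in this mouse, 105 other probes of 50 of these genes outside the corner had a median difference of -0.0607 (SD 0.354). The value tested was itself dark on this array for 37 genes, among them Fpr1, at -7.53, and Golgb1, at -7.47. No biological explanation beyond silence in this mouse was tested.

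Hair follicle genes were higher in wild-type mouse 1 than in wild-type mouse 2 by 2.28 in the list median and higher in mutant mouse 2 than in mutant mouse 1 by 2.44, while mutant mouse 1 and wild-type mouse 1 differed by 0.0375. The smaller of these differences within a group, 2.28, argues against genotype as the only source. Basal keratinocyte genes differed by -0.0089 between mutant mouse 2 and wild-type mouse 2, against a different amount of all epidermal RNA. In 48 keratin-associated protein genes outside the list, wild-type mouse 1 was higher by 2.89 and mutant mouse 2 by 2 than the other mouse of the group. Mutant mouse 1 differed from wild-type mouse 1 by -0.434. A hair growth phase or hair content that differs between single mice would give this order. These are hair genes too, so they would follow the list under other sources as well and cannot single this one out. An effect of genotype beside a difference between single mice stays open with 2 mice per group.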
